A study of Schmidtea mediterranea with 8 samples.

How the data were processed

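Total RNA of the near and far regions of regenerating tail pieces was labelled with Cy3 and hybridised in 1 colour to a custom Agilent slide with 8 arrays, per the labels' protocols. Fir1 RNAi and control RNAi animals and both regions gave 4 groups with 2 arrays each. Per the file headers, the deposited scanner values are spot intensities made with Feature Extraction 10.7.1.1, with background subtracted and spatial trends removed within each array, and with low signals replaced by a surrogate. The deposited value table of the series holds log2 values. Each of its columns has the median 5.1925, and the columns correlate at 0.99681 to 0.99985 with the log2 processed intensity of the same array. Its scale and direction follow from that match, and how the authors normalised it is not given in the sources used here. It served only as an alternative.

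Processed intensities were taken as log2 and the array's 75th percentile over all 61657 non-control probes was subtracted. That percentile ranged from 249.4 to 331.3 intensity units. The 1319 control features and outlier spots, from 0 to 16 per array, were left out, and no spot was saturated. Probes well above background on both arrays of at least 1 group were kept, which left 33020 probes (53.6%). This filter uses the group labels, so a probe bright in 1 group only is kept through that group. The adjusted p values of such probes depend in part on the filter, and calls lost with no filter are given beside them. Each probe had 1 spot. A 4-group linear model was fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 4 residual degrees of freedom per probe and 2.46 prior degrees of freedom. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg within each contrast, with a threshold of 0.05. An exact permutation test of 2 arrays against 2 cannot go below p = 0.333, so the model's pooled spread carries the tests. The p-values measure the spread between replicates described as biological by the submitters.

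For a probe not well above background on any array of a group, the fold is given as a bound. The bright group's mean was set against the mean, per dim array, of the higher of the dim probe's own value and the lowest value among probes well above background. That lowest value ran from -4.411 to -3.435 over the arrays. Such a bound rests on means of 2 arrays and is not a confidence limit. The adjusted p given beside a bound tests the fitted log2 change of the processed values, not the bound. The fixed rule for named items, with no gene names in the files, took at most 2 rises and 2 falls per contrast, those with the largest log2 change among called probes whose groups did not overlap. For the difference between regions in the Fir1 effect, the overlap condition did not apply. The 22 gene lists fixed before the data were examined had 0 members, because the files pair no probe with a gene, and their tests were not run.

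Probe sequences of 60 bases were translated in sense frames and searched for 35 peptide patterns with Python 3.11.15. Of these, 20 were written before any expression test of them and 15 after the values of the first set had been seen. The collagen repeat belongs to the first set. Patterns with at least 3 tested probes were tested with limma's camera, with a preset correlation of 0.01 and with an estimated one.

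The methods were tested on simulated data for the near Fir1 effect over 33020 probes with 200 changed. With changes of log2 1 and 0.5 only, 15% and 0% were called, with 0 false calls. With changes of log2 2, 1 and 0.5, the called shares were 90%, 52.5% and 2.5%, with 4 false calls. Recovery of a given size thus varied with the other changes simulated. The real near effect called 3608 probes, far more than the 200 changed here. The adjusted threshold depends on that share, so these recovery values do not carry over to the real data. Alternatives covered the scaling, background correction, filter, deposited values, variance model, threshold, replicate and tail piece blocks, arrays in the fit and each array left out. Leaving out an array of a group outside the contrast does not move the fitted change. It alters only the spread estimate, its degrees of freedom and so the p-values. Slide row was added after the data were seen. All 8 arrays were on 1 slide with 1 scan time.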

Results

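Gene expression was measured in tail pieces of the planarian Schmidtea mediterranea, a flatworm that rebuilds missing body parts from stem cells. Animals were fed double-stranded RNA 2 times to silence Fir1, or a control, over 8 days, and were then cut behind the pharynx. The tail pieces regenerated for 48 hours before the tissue next to the wound and the tissue far from it were separated. The 8 arrays fall into 4 groups of 2 biological replicates, which are near the wound with control RNAi, near with Fir1 RNAi, far with control RNAi and far with Fir1 RNAi. Between 30620 and 35541 of the 61657 probes were well above background on an array. Replicate arrays correlated at 0.9897 to 0.9938 across tested probes, and the small number of arrays limits the precision of every value. The files give probes no gene names, so results are given by probe, and the silencing of Fir1 itself was not analysed here. Levels are log2 signals relative to the array's 75th percentile, each with the SD over n = 2 arrays.

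The first 2 principal components, with 42.3% and 31% of the variance, set the 4 groups apart. On the first component the 4 near arrays lay below 0 and the 4 far arrays above 0. On the second, the 4 control arrays lay above 0 and the 4 Fir1 arrays below 0. Slide position was uneven over these groups. Row 1 held 3 of the 4 near arrays and 3 of the 4 control arrays, and row 2 held 3 of the 4 far arrays and 3 of the 4 Fir1 arrays. Column 3 held only near arrays and column 4 only far arrays, while each column held a Fir1 and a control array. No fit had a column term.

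**Figure D1:**
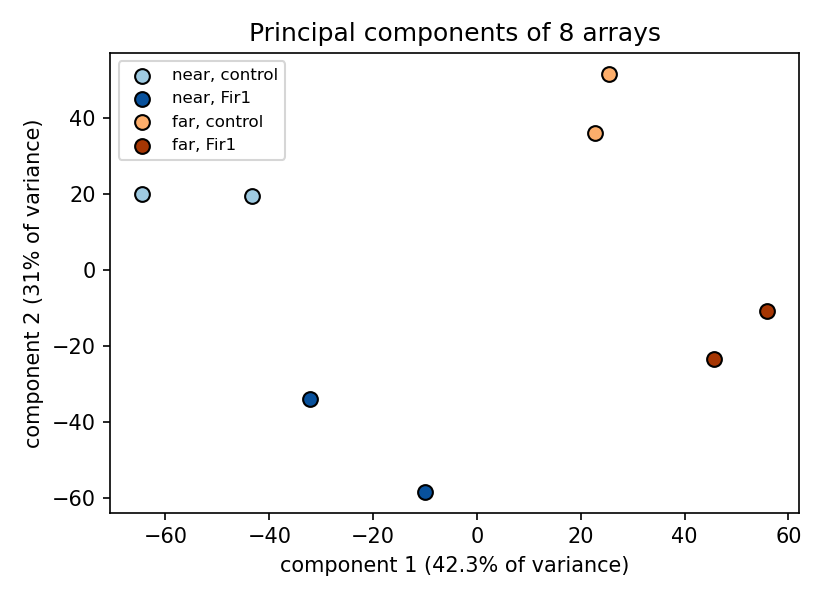
Each point is 1 array, placed by its scores on the first (x axis, 42.3% of variance) and second (y axis, 31% of variance) principal components of log2 signal over tested probes, with colours for the 4 groups. Near and far arrays separate along x, and control and Fir1 arrays along y.

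The comparison near the wound asks which transcripts differed after Fir1 RNAi in tissue at the cut. Probe CUST_11201_PI430032056 (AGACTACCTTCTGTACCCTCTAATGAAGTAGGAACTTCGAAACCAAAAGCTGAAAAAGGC) rose by at least 4.79-fold, from a level not well above background at -6.17 ± 0.64 (SD, n = 2) to -1.66 ± 0.089 (SD, n = 2). Its limma adjusted p was 0.00234. Probe CUST_17312_PI430032056 (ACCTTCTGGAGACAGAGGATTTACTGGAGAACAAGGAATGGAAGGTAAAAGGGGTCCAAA), one of those that encode a collagen repeat in sense translation, rose by at least 3.85-fold, from -5.82 ± 0.66 to -1.98 ± 0.30 (limma adjusted p = 0.00617). Probe CUST_17688_PI430028067 (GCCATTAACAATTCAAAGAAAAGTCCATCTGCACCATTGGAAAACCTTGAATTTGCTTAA) was at least 10.4-fold lower after Fir1 RNAi, going from -0.56 ± 0.069 to -5.90 ± 0.18 (limma adjusted p = 0.00113). Probe CUST_17494_PI430028067 (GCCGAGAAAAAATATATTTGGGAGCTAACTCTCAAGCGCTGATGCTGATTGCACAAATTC) was at least 4.61-fold lower, from -1.73 ± 0.42 to -6.03 ± 0.40 (limma adjusted p = 0.00214). With 1 array of the 2 near groups left out, these 4 bounds ran from 3.42 to 6.72, 2.74 to 5.40, 8.88 to 12.2 and 3.76 to 5.66. The bounds hold for the processed signal. Normexp background correction with an offset of 50 compresses dim signals. With it the folds of these 4 probes were 2.36, 2.14, 3.68 and 2.43, each below its bound. With no filter on dim probes CUST_17312_PI430032056 lost its call (limma adjusted p = 0.063). In all, 1371 of 33020 tested probes rose and 2237 fell at an adjusted p under 0.05. The split was 292 and 301 with an absolute log2 change of at least 1, and 1591 and 1909 with the 75th percentile taken over probes well above background on all arrays. The 3608 called probes became 69 with no filter on dim probes, 740 with the slide row as a block and 410 with the arrays of these 2 groups alone. The count was 490 without near control replicate 1, 406 without near control replicate 2, 563 without near Fir1 replicate 1 and 1595 without either far control array.

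The same question was asked of tissue far from the wound. Probe CUST_7521_PI430028067 (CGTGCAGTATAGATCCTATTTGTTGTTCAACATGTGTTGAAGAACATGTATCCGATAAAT) rose by at least 3.80-fold, from -5.92 ± 0.29 to -1.84 ± 0.81 (SD, n = 2; limma adjusted p = 0.00745). Probe CUST_13567_PI430028067 (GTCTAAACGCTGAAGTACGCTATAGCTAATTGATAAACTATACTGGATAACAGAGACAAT) rose by at least 3.13-fold, from -5.96 ± 0.085 to -2.11 ± 0.90 (limma adjusted p = 0.0113). Probe CUST_11070_PI430028067 (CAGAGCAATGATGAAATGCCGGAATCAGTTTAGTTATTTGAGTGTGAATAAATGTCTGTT), bright on every array, fell by 2.92 on the log2 scale (SE 0.0813), from 4.34 ± 0.0093 to 1.42 ± 0.041 (limma adjusted p = 0.000363). Probe CUST_8844_PI430032056 (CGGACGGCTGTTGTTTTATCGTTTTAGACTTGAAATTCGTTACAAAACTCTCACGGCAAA) was at least 2.60-fold lower, from -2.36 ± 0.12 to -5.23 ± 1.1 (limma adjusted p = 0.0312). With 1 array of the 2 far groups left out, the bounds of CUST_7521_PI430028067 and CUST_8844_PI430032056 ran from 2.56 to 5.66 and from 2.45 to 2.77. With normexp the folds of CUST_7521_PI430028067, CUST_13567_PI430028067 and CUST_8844_PI430032056 were 2.35, 2.16 and 1.55, each below its bound. With no filter these 3 probes lost their calls, at limma adjusted p values of 0.0741, 0.0846 and 0.157. CUST_13567_PI430028067 also lost it without far control replicate 1 (0.0666) or 2 (0.0621), and its bound was 4.88-fold and 2.02-fold without far Fir1 replicates 1 and 2. CUST_8844_PI430032056 lost it without either near control array (0.0617), far control replicate 1 (0.148) or 2 (0.12), or far Fir1 replicate 1 (0.0771). The near control arrays are outside this contrast, and the log2 change of CUST_8844_PI430032056 stayed at -2.87 without them. Here 1142 probes rose and 1369 fell, and this balance was not stable. Rises outnumbered falls, at 1274 and 1078, with the 75th percentile taken over probes well above background on all arrays. They also did with the slide row as a block (295 and 205), with the arrays of these 2 groups alone (711 and 594), with no filter (21 and 3) and with an absolute log2 change of at least 1 (366 and 221). The same held without either near control array (639 and 561), far control replicate 1 (110 and 65) or 2 (168 and 112), and far Fir1 replicate 1 (350 and 240) or 2 (300 and 235).

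Averaged over both regions, 4005 probes rose and 4766 fell after Fir1 RNAi. Of the probes named near the wound, CUST_11201_PI430032056 also rose far from it, by at least 2.71-fold (limma adjusted p = 0.00451), and averaged (0.000539). Its averaged log2 change was 1.1 with normexp. CUST_17312_PI430032056 was also called higher far (limma adjusted p = 0.028), well above background on 1 of 2 far Fir1 arrays. CUST_17688_PI430028067 and CUST_17494_PI430028067 did not pass far (limma adjusted p = 0.0532 and 0.876). Probe CUST_11070_PI430028067 fell by 3.07 on the log2 scale (SE 0.0575, limma adjusted p = 2.82e-05), and its near level went from 4.71 ± 0.040 to 1.48 ± 0.053 (SD, n = 2). Probe CUST_13109_PI430032193 (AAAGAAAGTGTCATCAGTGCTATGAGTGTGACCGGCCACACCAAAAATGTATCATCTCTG) rose (limma adjusted p = 0.00141). Far from the wound it rose by at least 4.51-fold, from -5.35 ± 0.24 to -1.59 ± 0.22. Near it, the level went from -4.67 ± 0.94, well above background on 1 of 2 arrays, to -1.28 ± 0.070. With normexp its averaged change was 1.24 on the log2 scale. The 8771 called probes became 1547 with no filter and 2461 with the slide row as a block. The count was 3997 without far control replicate 1, 4529 without far control replicate 2, 5711 and 4252 without near control replicates 1 and 2, and 5525 without near Fir1 replicate 1. With the 75th percentile taken over probes well above background on all arrays, 4609 rose and 4117 fell, and with an absolute log2 change of at least 1, 384 rose and 268 fell, so the balance of rises and falls turned with these choices.

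Of the probes called near and far, 574 rose in both regions, 791 fell in both and 5 moved in opposite directions. Independent lists of these sizes would share 47.4 rises and 92.7 falls. Both tests use the same pooled spread for each probe, and both effects carry the same slide row imbalance. The lists are thus not independent, and could share more than this without a common Fir1 effect. Across probes, which are not independent replicates, the near and far effects had a Pearson correlation of 0.629 and a Spearman correlation of 0.667, with no array in both effects. With no filter the Pearson correlation was 0.323.

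**Figure D2:**
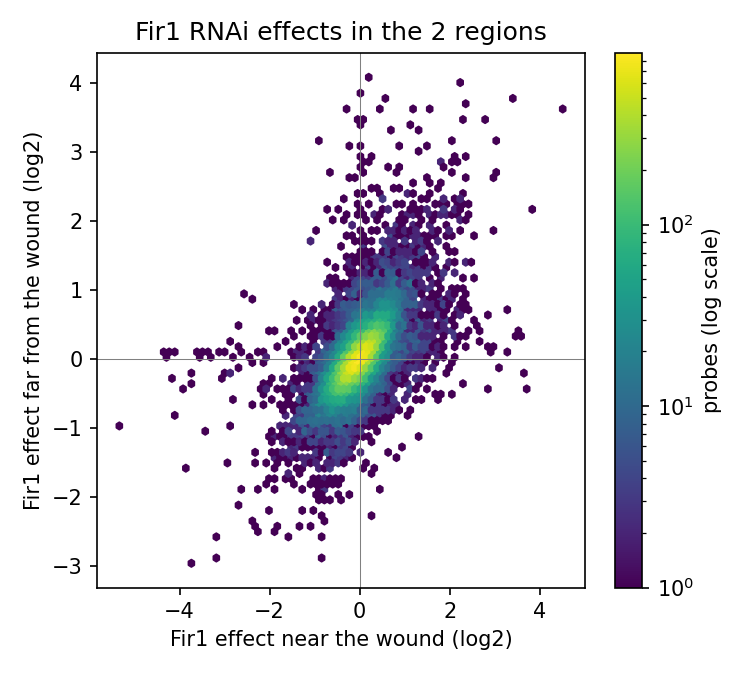
Each hexagon counts tested probes (colour, log scale) by their log2 Fir1 effect near the wound (x axis) and far from it (y axis), as differences of group means over 2 arrays each. The cloud runs along the rising diagonal, with a Pearson correlation of 0.629 across probes.

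Probes whose sense translation holds a known peptide pattern were grouped by that pattern, and 9 patterns had at least 3 tested probes. These patterns were written after the files had shown no gene names and name no single gene. The collagen repeat, a run of regularly spaced glycines typical of extracellular matrix collagens, was held by 14 tested probes. Averaged over regions, 7 of the 14 rose, 7 did not pass, and the median change was 0.49 on the log2 scale. The camera adjusted p over the 9 patterns was 3.71e-05 with a preset correlation of 0.01, and the call was lost at an adjusted p = 0.328 with an estimated correlation. Adjusted over the list alone, 10 rose. The mean level of the 14 probes near the wound was -0.25 ± 0.012 in controls and 0.40 ± 0.081 after Fir1 RNAi (SD, n = 2 arrays). Far from it the mean levels were -0.15 ± 0.063 and 0.37 ± 0.11. These means include CUST_17312_PI430032056, which was not well above background in either control group. Without it, the difference of means over 13 probes was 0.407 near in place of 0.652, and 0.394 far in place of 0.519. Of 5 core histone probes, 4 did not pass for the averaged effect. The other one fell by 1.97 on the log2 scale (SE 0.0913, limma adjusted p = 0.000523). The EGF repeat, tubulin, actin, ubiquitin, EF hand, WD repeat and protein kinase patterns had camera adjusted p values from 0.113 to 0.49 for the averaged effect.

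**Figure D3:**
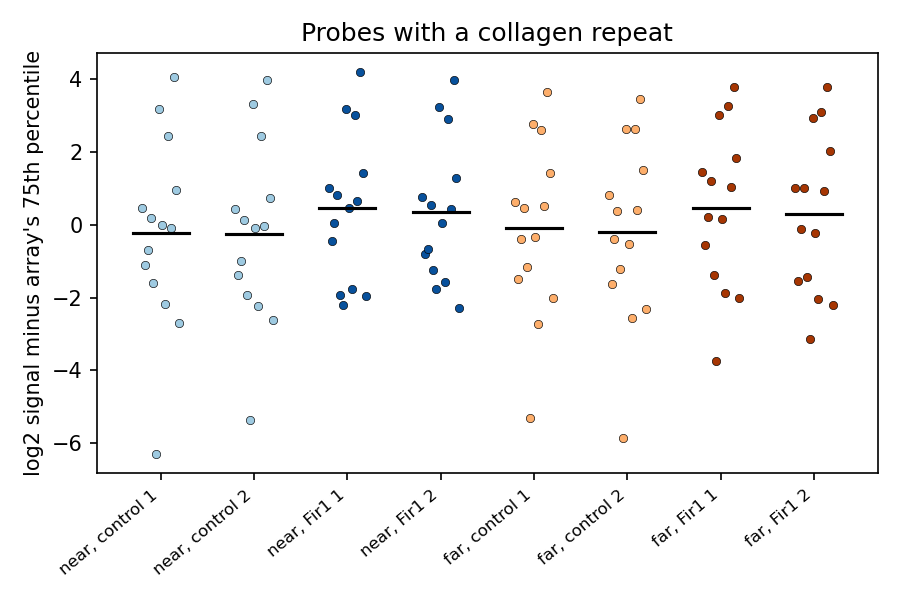
Each point is 1 of the 14 tested probes with a collagen repeat on 1 of the 8 arrays, as log2 signal minus the array's 75th percentile (y axis), and black lines are array means. The means of the 4 Fir1 arrays lie above those of the 4 control arrays.

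The comparison of regions asks what distinguishes tissue at the wound from distant tissue. In controls, probe CUST_7784_PI430028067 (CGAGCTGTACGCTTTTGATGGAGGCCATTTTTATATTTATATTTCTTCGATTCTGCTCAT) was higher near the wound (limma adjusted p = 0.0301), at 0.52 ± 0.21 (SD, n = 2). Its far arrays were at -4.94, not well above background, and -3.48, so no exact difference is given. With normexp the difference was 2.40. Its call was lost with no filter (limma adjusted p = 0.139), without near control replicate 1 (0.0831) or 2 (0.157), and without far control replicate 1 (0.14) or 2 (0.0782). Probe CUST_12638_PI430028067 (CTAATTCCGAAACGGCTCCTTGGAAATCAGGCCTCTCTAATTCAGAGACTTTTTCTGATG) was at least 5.93-fold higher near it, at -1.19 ± 0.10 against -5.54 ± 0.28 (limma adjusted p = 0.0204), and 2.53-fold with normexp. Its call was lost with no filter (0.11), without near control replicate 1 (0.0673) or 2 (0.115), and without far control replicate 1 (0.0999) or 2 (0.0796). Probe CUST_181_PI430028067 (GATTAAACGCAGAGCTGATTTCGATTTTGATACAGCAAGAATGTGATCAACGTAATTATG) was lower near the wound, at -1.23 ± 1.2 against 2.37 ± 0.090 (limma adjusted p = 0.00996). That call was lost with no filter (0.0755) and without far control replicate 1 (0.0618). Its log2 difference of -3.61 became -4.45 and -2.76 without near control replicates 1 and 2. Probe CUST_8939_PI430032056 (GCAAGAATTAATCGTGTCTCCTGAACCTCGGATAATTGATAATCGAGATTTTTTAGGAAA) was lower near the wound (limma adjusted p = 0.0357), with near arrays at -2.24 and, not well above background, -4.32, against 0.21 ± 0.13 far. With normexp the difference was -1.97. The call was lost with no filter (0.152), with the replicate number as a block (0.0543), and without near control replicate 2 (0.17), far control replicate 1 (0.129) or 2 (0.133), or either far Fir1 array (0.0585). In all, 3541 probes were higher near the wound and 2285 were lower. Of the 5 core histone probes, 2 were higher near the wound and 3 did not pass. Among the 5, CUST_25625_PI430032056 and CUST_6002_PI430028067 overlap in sequence, so the 5 are not separate readings. The camera adjusted p of the pattern was 0.0281 with the preset correlation, 0.0504 with the slide row as a block, and the adjusted p = 0.669 with an estimated correlation. The 5826 called probes became 129 with no filter and 1959 with the slide row as a block. The count was 3161 and 362 without near control replicates 1 and 2, and 542 and 1067 without far control replicates 1 and 2.

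After Fir1 RNAi, 791 probes were higher near the wound and 459 were lower. Probe CUST_2047_PI430032193 (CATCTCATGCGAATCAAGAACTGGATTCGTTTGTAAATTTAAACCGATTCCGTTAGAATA) was higher near the wound by 5.51 (SE 0.993, limma adjusted p = 0.0397), at 3.91 ± 0.19 against -1.60 ± 1.7 (SD, n = 2). Probe CUST_18219_PI430032056 (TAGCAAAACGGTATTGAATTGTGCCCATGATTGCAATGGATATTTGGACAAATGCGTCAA) was higher by 5.30 (SE 0.9, limma adjusted p = 0.0344). Both were also called higher near the wound in controls (limma adjusted p = 0.044 and 0.0375). Their log2 differences after Fir1 RNAi were 6.75 and 6.43 without far Fir1 replicate 1, and 4.28 and 4.17 without far Fir1 replicate 2. With normexp that of the first was 4.65. These 2 probes lost their calls with no filter (limma adjusted p = 0.188 and 0.171) and with the replicate number as a block (0.0663 and 0.0611). They also lost them without either near control array (0.0715 and 0.0657), near Fir1 replicate 1 (0.0866 and 0.0818) or 2 (0.134 and 0.112), or far Fir1 replicate 2 (0.136 and 0.122). Probes CUST_181_PI430028067 and CUST_8939_PI430032056, lower near the wound in controls, were lower there again (limma adjusted p = 0.0102 and 0.0325). The first differed by -4.84, and by -3.81 with normexp. The near arrays of the second were at -3.59 and, not well above background, -5.67, against 0.35 ± 0.11 far, and its difference was -2.35 with normexp. With no filter the calls of both were lost (0.0847 and 0.164). That of CUST_181_PI430028067 was also lost without far Fir1 replicate 2 (0.0639). That of CUST_8939_PI430032056 was lost with the replicate number as a block (0.0581) and without near Fir1 replicate 1 (0.0647), either far control array (0.0605), or far Fir1 replicate 1 (0.0977) or 2 (0.137). The 2 region lists shared 670 probes higher near the wound and 343 lower, with 3 in opposite directions, against 84.8 and 31.8 for independent lists. These lists too share the pooled spread and a slide row imbalance, so they are not independent. The 5 core histone probes, of which CUST_25625_PI430032056 and CUST_6002_PI430028067 overlap in sequence, all had positive differences, from 0.32 to 0.68, and 1 passed. The camera adjusted p was 0.00438 with the preset correlation of 0.01, and 0.943 with an estimated correlation of 0.68. The 1250 called probes became 10 with no filter and 526 with the slide row as a block. The count was 558 and 168 without far Fir1 replicates 1 and 2, 475 without near Fir1 replicate 2, 677 without either near control array and 652 without either far control array.

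A test of the difference between the near and far Fir1 effects called 4 of 33020 probes, 1 with a positive and 3 with a negative difference, and 2430 probes had an unadjusted p under 0.05. Probe CUST_20702_PI430028067 (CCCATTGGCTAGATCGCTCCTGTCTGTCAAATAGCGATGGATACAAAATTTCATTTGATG) was well above background only on the 2 near Fir1 arrays, at -2.09 ± 0.078 (SD, n = 2; limma adjusted p = 0.0496). Probe CUST_17688_PI430028067 was well above background only on the 2 near control arrays, at -0.56 ± 0.069 (limma adjusted p = 0.0496). The same held for probe CUST_16007_PI430028067 (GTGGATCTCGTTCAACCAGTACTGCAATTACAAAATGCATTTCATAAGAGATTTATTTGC), at -1.77 ± 0.33 (limma adjusted p = 0.0496). Near the wound the bounds on the Fir1 effect were at least 3.55-fold higher for the first probe, and at least 10.4-fold and 4.5-fold lower for the other 2. With 1 array of the 2 near groups left out, they ran from 2.53 to 4.98, 8.88 to 12.2 and 3.83 to 5.30. Far from the wound neither group was well above background, so no fold is given there. With normexp the fitted differences were 1.00, -1.87 and -1.22 (limma adjusted p = 0.136, 0.00637 and 0.211). With the replicate number as a block the first 2 lost their calls (limma adjusted p = 0.0936 for each), and with the slide row as a block 0 probes were called, with 2352 at an unadjusted p under 0.05 in limma. The row imbalance was the same in both Fir1 effects and cancels in their difference. The layout thus fixed the correlation of 1 between differences with and without the row block, with median standard errors of 0.179 and 0.18. Residual degrees of freedom were 3 in place of 4, so the calls lost with that block do not show an effect of row. All 3 calls were lost with no filter (0.385) and with an intensity trend in the variance (0.185, 0.0599 and 0.163). CUST_20702_PI430028067 lost its call with the deposited value table (limma adjusted p = 0.0781) and without any 1 of the 4 near or 2 far Fir1 arrays (limma adjusted p = 0.099 to 0.13). With 1 array left out the adjusted p of CUST_17688_PI430028067 was 0.0501 to 0.118 and that of CUST_16007_PI430028067 was 0.0629 to 0.164. The call of 4 probes became 0 with the 75th percentile over probes well above background on all arrays, 0 with no filter and 13 with quantile normalisation. It was 0 without near control replicate 2, near Fir1 replicate 1 or far Fir1 replicate 2, and 1 without near control replicate 1, far Fir1 replicate 1 or far control replicate 2.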

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

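The test on the share of probes above background, the consensus correlation test, the slide row fits, the mirrored choice of probes on Fir1 arrays, the ratio of median absolute region differences and the limit to splits with balanced regions were chosen after results had been seen. Groups of 2 arrays are too small for a test of single arrays that stand apart.

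The difference between the near and far Fir1 effects passed the test for 4 probes. The named ones were each well above background in 1 of the 4 groups only, and passed the filter through that group. Near the wound the Fir1 effect thus has only a bound. It was at least 3.55-fold higher for CUST_20702_PI430028067, at least 10.4-fold lower for CUST_17688_PI430028067 and at least 4.5-fold lower for CUST_16007_PI430028067. With normexp the fitted differences between regions were 1.00, -1.87 and -1.22 on the log2 scale, and the calls of the first and last were lost. With the replicate number as a block the first 2 lost their calls (limma adjusted p = 0.0936 for each), and with no filter all 3 did (0.385). With slide row as a block 0 probes were called, with 2352 at an unadjusted p under 0.05 in limma. The row imbalance was the same in both Fir1 effects and cancels in their difference. The layout thus fixed the correlation of 1 between differences with and without the row block. This loss does not show an effect of row.

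Fewer probes differed between regions after Fir1 RNAi (1250) than in controls (5826), at 526 and 1959 with slide row as a block, but the leave-one-out counts of the comparisons overlap, at 168 to 874 and 362 to 6165. The direct test of a changed region difference is the contrast of the near and far Fir1 effects, which called 4 of 33020 probes. At an unadjusted p under 0.05 in limma, 7996 probes differed between regions after Fir1 RNAi and 11809 in controls. The counts alone do not show that the region difference of a probe changed. A lower share of probes above background on the Fir1 arrays is argued against, since their mean of 53.9% lies within the range of the control arrays. Larger spread between Fir1 arrays is argued against in the pooled fit, where both differences have the same standard error for 33005 of 33020 probes and added noise enlarges estimates: the median absolute difference after Fir1 RNAi was 0.755 of that in controls, and 0.662 to 0.922 of it with 1 array left out, while the ratio of differences shared by replicates, set beforehand, was 0.924 and 0.883 and decided neither way. A smaller difference after Fir1 RNAi of probes high near the wound stays open, as a hypothesis. Among such probes chosen on 1 control replicate the median was on average 0.682 of that in the other control replicate. Their median Fir1 effects were 0.0341 and 0.0256 near and 0.0976 and 0.23 far. The median near effect was thus not below 0, which does not settle whether the near level of a part of these probes fell. Probes higher far gave ratios of 0.828 and 1.22, and probes chosen as higher near on Fir1 replicates gave control differences of 0.83 and 1.24 times the left-out Fir1 value, with no single direction in either.

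The Fir1 effects near and far went together across probes. A trend with probe GC content is argued against by a correlation of 0.629 after its removal, and a trend with signal by 0.631. Single faulty probes are argued against by overlapping probes on the same strand, whose averaged effects correlated at 0.917 over 516 pairs. Animals or RNA shared by both regions of a condition cannot be told apart from Fir1 RNAi, with a consensus correlation of 0.0511 that decides neither way. Slide row also stays open in part: 3 of the 4 Fir1 arrays lay in row 2 and 3 of the 4 control arrays in row 1, and the correlation was 0.579 with row as a block. The region differences share this limit, with 3 of the 4 near arrays in row 1 and 3 of the 4 far arrays in row 2. For them slide column also stays open, since columns 3 and 4 held only near and only far arrays and column was not fitted.

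Of the 14 tested probes with a collagen repeat, 7 rose after Fir1 RNAi averaged over regions, and the pattern had adjusted p = 0.328 with an estimated correlation. Their GC content and signal are argued against, since the median effect lay at percentile 100 of 10000 matched random sets, whose highest median was 0.29. A single deciding array is argued against by a lowest median of 0.384 with 1 array left out, against 0.487 with all. Hybridisation of the repeat sequence itself cannot be told apart, because 0 of the 10 opposite-strand repeat probes passed the filter and the planned comparison was void. No biological explanation was tested.

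For the averaged Fir1 effect, 18 of the 35 splits of the 8 arrays into 4 and 4 keep 2 near and 2 far arrays on each side, as the real one does, and the rest mix the split with region. These 18 are too few for a share under 0.05. With region as an added term the real split called 8820 probes and the highest other called 22, so 1 split gave as many. The other splits leave the Fir1 differences in the residual spread.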

How the results depend on the processing

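The slide row fits and all settings of the peptide patterns were chosen after the data were seen. Values are called probes for the Fir1 effect near, far and averaged, the region difference in controls and after Fir1 RNAi, and the difference of Fir1 effects, in that order. With no filter they were 69, 24, 1547, 129, 10 and 0 (2225 at an unadjusted p under 0.05 in limma for the last), and the near-far correlation was 0.323. With an absolute log2 change of at least 1 the first 5 were 593, 587, 652, 900 and 513. With slide row as a block they were 740, 500, 2461, 1959, 526 and 0 (2352 unadjusted). Effects with and without this block correlated at 0.944 to 1, where the layout fixed the 1 for the difference of Fir1 effects. Standard errors grew from 0.127 to 0.142 for the near effect. Within slide row 1 the near effect called 1 probe, and within row 2 the far effect called 0 (4954 at an unadjusted p under 0.05 in limma); each fit had 1 array in an arm and 1 residual degree of freedom, so nothing follows from these counts. With the arrays of the compared groups alone, counts were 410 near, 1305 far and 261 for the region difference after Fir1 RNAi. An intensity trend in the variance gave 5825 near, 3951 far, 2922 for the region difference after Fir1 RNAi and 2 for the difference of effects. Normexp gave 2487 for the region difference after Fir1 RNAi. The difference of Fir1 effects called 13 probes with quantile normalisation, 11 with the series table, 0 with the percentile over probes above background on all arrays (2421 unadjusted) and 0 with only those probes (2215 unadjusted). With the replicate number as a block it called 2, and the other contrasts called 3300, 1937, 8739, 5644 and 893. Same-numbered arrays deviated together at 0.323, -0.0871, -0.00912 and 0.104, and with 2 pairs and no stated meaning the numbers were not used to pair the arrays, and whether they do stays unknown. Leaving out 1 array, with a lone array assumed to vary like the others, gave 406 to 4456, 175 to 2891, 3997 to 9741, 362 to 6165, 168 to 874 and 0 to 6 called probes, and a correlation of 0.541 to 0.627. With an estimated correlation, the collagen pattern had adjusted p = 0.361 near, 0.411 far and 0.328 averaged, and the histone pattern 0.669 and 0.943 for the region differences. The histone value in controls was 0.0504 with the slide row block. The 23 log2 changes of named probes were each compared with the main fit over the alternative settings. Of these repeated comparisons, 262 kept direction and call, 89 kept direction but lost the call, and 0 reversed. The absence of reversals was largely fixed in advance. Named changes outside the difference of Fir1 effects were chosen for groups that did not overlap, so leaving out 1 array could not reverse them. The filter, replicate block and variance trend settings do not move the fitted change. With no filter 15 of 23 lost the call. With normexp 17 of 23 moved by over 1.5 times on the log2 scale and 19 as folds, all toward 0, which its offset of 50 does to dim signals by construction. These included 4.51 to 1.24 for CUST_11201_PI430032056, 3.84 to 1.1 for CUST_17312_PI430032056, -4.29 to -1.28 for CUST_17494_PI430028067 and -2.87 to -0.633 for CUST_8844_PI430032056, and the folds lay below the bounds given for the processed signal. Leaving out 1 array moved 8 of them by over 1.5 times as folds, such as CUST_2047_PI430032193 from 5.51 to 4.28 on the log2 scale without far Fir1 replicate 2. For the far effect rises outnumbered falls in several settings, such as 1274 and 1078 with the percentile over probes above background on all arrays. The cause of the other changes was not tested. Slide and scan batches and the gene list shifts were not run, since there was 1 slide, 1 scan time and no list member. Dim probes near background limit the values.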

Other observations

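Overlapping probes on opposite strands did not move together. Over 61 pairs that share at least 25 bases, the averaged Fir1 effects had a correlation of 0.157 across pairs, against 0.917 over 516 pairs on the same strand. For the region difference in controls the values were -0.133 and 0.877.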
